A study of Escherichia coli with 12 samples.

How the data were processed

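RNA was measured in Escherichia coli K-12 MG1655, the standard laboratory strain, grown aerobically in LB at 37 °C, per the labels' protocols. Cultures received t-cinnamaldehyde (CNMA), the aldehyde that gives cinnamon its flavour, at 0.94 mM, which the labels give as 0.25 times the minimal inhibitory concentration (MIC), at an optical density of 0.1. Cells were taken after 30 or 60 min. CNMA was dissolved in DMSO, and whether the untreated cultures received DMSO is not given in the sources used here. The series text speaks of independent repeats, and each of the 4 groups has 3 libraries. Libraries were stranded total RNA libraries with depletion of bacterial rRNA, per the labels' protocols.

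The deposited table holds raw counts for 4534 rows and 12 libraries, per the file headers, with no normalization. It also holds the authors' log2 fold changes of CNMA against control at both times, with p-values and adjusted p-values, per the file headers. The authors' test statistic, a score with no fixed range, is also there and was not used. The submitters' processing notes name FastQC 0.11.9, Trimmomatic 0.38.1, HISAT2 without a version, R 4.3.1 and DESeq 1.40.2. The tool that made the counts, its strand setting, the genome build and the annotation are not given in the sources used here. Each count column was matched to its sample through the sample descriptions.

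Row labels were compared with the gene table of assembly ASM584v2, used only for names and for which genes neighbour each other. Of the labels, 4351 matched by locus tag and 179 by symbol, and 4 had no match. The build behind the counts is unknown, so no coordinates are given. For most of the table, the counts did not belong to the labelled gene but to an interval displaced along the chromosome. The displacement was estimated, after seeing the data, by sliding the intervals and scoring whether neighbouring rows that would then share a gene had similar counts per base. It was 800 bases in the 1033 rows from insB9 up to insH21 (stretch 2) and 1925 bases in the 3251 rows after (stretch 3). For the 246 rows before insB9 (stretch 1), 0 bases was taken from a combined score of gene group properties. The neighbour score was best there at 50 bases, and at 200 in its first window. Those boundaries were set by inspection at insertion sequence genes. That combined score had been tried first everywhere and gave 725 and 2125 bases for stretches 2 and 3. The neighbour score was then preferred for these because it uses neither gene function nor fold change. On simulated data with 4 known displacements the scan returned each with an error of 0 bases. There counts were even along each gene, boundaries were known and displacements were multiples of the scan step, so errors in the data can be larger. Simulated stretches without displacement scored at most 0.096, and displaced ones at least 0.278. Stretch 1 scored 0.34 at 50 bases, so exactly 0 bases there was assumed and not shown.

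In the text, a gene is named by its displaced position, with the deposited label in parentheses. A gene name given a value with no label beside it stands in stretch 1, where both are taken as the same. Each such name is an inference from the counts. A row can cover parts of several genes, and a value then belongs to the row, not to the named gene alone. Where the named gene fills under 80% of the row, its share is given where the label first appears, with the second gene where that fills at least 20%, or the genes that share the row are named. The strand setting is unknown, so reads from overlapping and antisense genes cannot be told apart, and near-identical copies such as insertion sequences are uncertain. Placed at the displacement, 3653 rows had at least 50% of their length in a single gene, and these rows covered 2718 genes.

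Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter, a design of 4 group means over all 12 libraries and the quasi-likelihood F test. The filter left 4300 rows and removed 234, including 23 with no count in any library. A row was called at a Benjamini-Hochberg adjusted p under 0.05, with no minimum fold change. Standard errors (SE) are the size of the log2 fold change divided by the square root of F. Levels are CPM on the TMM scale, as mean ± SD over 3 libraries. The 5 comparisons were CNMA against control at each time, the difference between those effects (60 min minus 30 min, an interaction contrast), and 60 against 30 min within control and within CNMA cultures. The design, the alternatives and 30 gene lists were fixed before the data were examined.

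Lists were tested with camera from limma 3.58.1, with a preset correlation between genes of 0.01 and adjustment over the lists. A correlation estimated per list and fry, which asks whether a list moves on balance in 1 direction without comparing it with other genes, were alternatives. The planned lists took members by deposited label. Because of the displacement, the text leads with lists whose members were placed at the displaced positions, each gene being taken as the row with the largest share inside it, at least 50%. This alternative was chosen after seeing the data. It left 29 lists with at least 3 members. The phage shock list had too few and was tested by label only. Many listed genes had no such row, so counts are out of the members measured, which can be a small part of a list.

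Single rows were named by a rule fixed beforehand. For CNMA against control at each time these were the 8 largest changes in each direction, and for the other comparisons the 5 largest. They had to be called, to reach a mean of 20 CPM in a compared group, and to have all 3 values of 1 group beyond those of the other, which chance gives for 10% of rows. At most 2 rows sharing the first 3 letters of the label were taken. Ribosomal and transfer RNA rows, by label or by displaced position, were left out. For each list described in the CNMA comparisons, up to 4 members with the smallest p were added. For the interaction, the condition on separate values was read as holding at either time, a reading made with the data in hand.

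Totals were 17297933 to 25458608 counts per library. Each simulation below changed 200 genes, as many up as down, from levels shared by all groups. Far more rows were called in the data, so the simulated rates were not measured for changes that broad. In simulated counts for CNMA against control at 30 min, over 4281 genes, the test found 55.2% of genes changed by a log2 of 0.5, 82.1% at 1 and 97% at 2, and 4.9% of its calls were false. At 60 min, over 4283 genes, these shares were 70.1%, 88.1% and 97%, with 5% false calls. For the interaction, over 4279 genes, they were 31.3%, 79.1% and 98.5%, with 4.1% false calls. For control at 60 against 30 min, over 4276 genes, they were 58.2%, 86.6% and 97%, with 8% false calls, and for CNMA at 60 against 30 min, also over 4276 genes, 47.8%, 83.6% and 98.5%, with 2.5% false calls.

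Alternatives were DESeq2 1.42.0 size factors, library totals without TMM, the DESeq2 Wald test, limma voom, no filter, a filter at a mean of 10 CPM, a minimum absolute log2 fold change of 1, no rRNA and tRNA rows, a replicate block, only the compared libraries, and leaving out each library in turn. Alternatives for normalized values did not apply to counts. Added after seeing the data were the displaced positions, also at 80% of the row, and fits without the 10 largest rows. No sample was left out. Replicates were compared for duplicates, and in all 12 pairs within groups the counts differed by more than sampling noise, with a chi-square per degree of freedom of 8.72 to 53.0. Scripts in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 handled tables and plots.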

Results

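Transcript levels were measured by RNA sequencing in E. coli MG1655 cultures with or without CNMA at 0.94 mM, a dose below the one that stops growth. Cells were collected after 30 and 60 min, which gave 4 groups of 3 libraries: control at 30 min, control at 60 min, CNMA at 30 min and CNMA at 60 min. Library totals were 18937578 to 21200003 counts in control at 30 min and 20256210 to 25216058 in control at 60 min. They were 24971713 to 25458608 in CNMA at 30 min and 17297933 to 20631448 in CNMA at 60 min. Replicates of a group correlated at 0.9915 or more. The first axis of a multidimensional scaling held 57.9% of the variation and the second 20.9%. On the first axis CNMA at 60 min replicate 3 lay at 0.73, closer to the CNMA libraries of 30 min (1.31 to 1.47) than replicates 1 and 2 at 0.37 and 0.49.

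Deposited labels and counts did not go together for most of the table. The row labelled ssrA, the abundant transfer-messenger RNA, held a mean of 20.9 counts, while the row labelled bamE held 646744, which was 2.99% of all counts. Rows labelled lpp and gapA, a major lipoprotein and a glycolytic enzyme, held means of 478 and 841 counts. With intervals displaced by 1925 bases, the bamE row lay over ssrA for 81.6% of its length. The score for similar counts per base in neighbouring rows that would share a gene was best at 1925 bases in stretch 3 (0.30), at 800 in stretch 2 (0.30) and at 50 in stretch 1 (0.34). At exactly 0 it was low in all 3 (-0.0057, -0.038 and 0.052), so that value does not separate them. At 200 bases it was 0.29 in stretch 1 but 0.012 and 0.046 in stretches 2 and 3. Of 28 windows of 150 rows in these stretches, 26 had their best displacement within 300 bases of the value of their stretch. Displaced rows made up 94.6% of the rows matched to the gene table. Over all matched rows, 3283 had at least 50% of their length in a gene named otherwise than their label. This count was not limited to displaced rows.

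**Figure D1:**
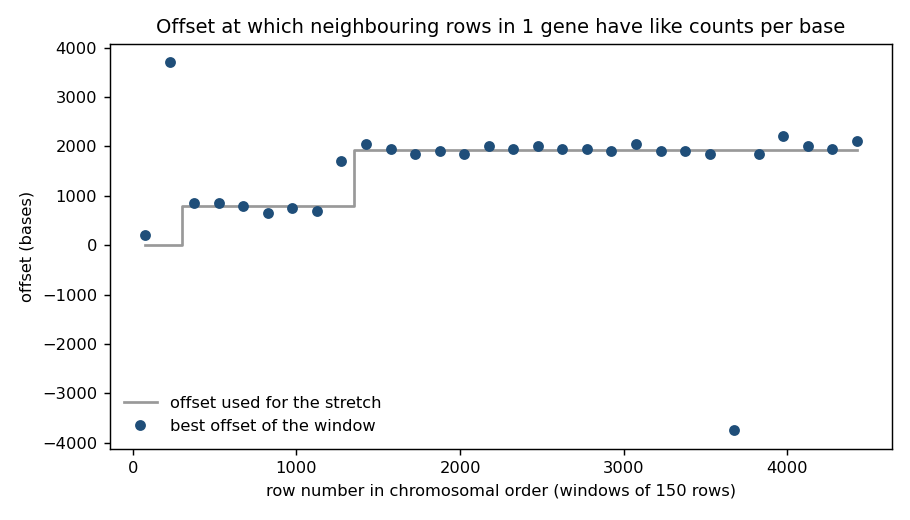
Displacement in bases (vertical axis) at which neighbouring rows agreed best, for windows of 150 rows along the deposited table (horizontal axis); points are windows and lines the values of the 3 stretches, 0, 800 and 1925 bases. In stretches 2 and 3, 26 of 28 windows lie within 300 bases of the line, and the window across the end of stretch 1 lies at 3700.

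The first comparison asked what a dose of CNMA below the inhibitory one changes within 30 min. The row with the largest increase was that of yqhD (label yghB), coding for an NADPH-dependent aldehyde reductase. It rose from 20.2 ± 1.58 CPM in control to 9844 ± 144 CPM with CNMA (SD, n = 3), a log2 fold change of 8.93 ± 0.10 (SE). A neighbouring row, labelled yqhC, rose by 8.27 ± 0.14. It lay 54.4% in dkgA, coding for another aldehyde reductase, and 34.7% in yqhD. With CNMA it held 5854 CPM. The row labelled yqhD, 68.2% in yqhG and 14.7% in dkgA, held 371 CPM. Reads of yqhD may make up much of the rise in the row labelled yqhC, so it cannot be assigned to dkgA. The gene yqhC (label metC), which codes for the activator of yqhD and dkgA, rose by 6.67 ± 0.14. The chaperone gene dnaK rose from 457 ± 33.8 to 4259 ± 44.7 CPM, a log2 fold change of 3.22 ± 0.09. In the other direction, ompF (label aspC, 51.7% of the row, with 32.8% in aspC), coding for a major porin, fell from 1587 ± 102 to 205 ± 3.57 CPM, a log2 fold change of -2.95 ± 0.06.

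Among lists fixed in advance and placed at the displaced positions, aldehyde and electrophile detoxification had 18 of 21 measured members higher and 2 lower (median log2 fold change 1.44, camera adjusted p = 2.1e-20; adjusted p = 0.029 with an estimated correlation). In this list the row labelled yqhC counted as dkgA. Besides the yqhD group, nemR (label sodC), the repressor of an electrophile-induced operon, rose by 5.46 ± 0.09. Heat shock chaperones and proteases had 12 of 13 members higher and none lower (median 2.08, adjusted p = 1.2e-20; adjusted p = 0.023 with an estimated correlation). The chaperonin gene groS (label fxsA, 61.6% of the row) rose by 3.51 ± 0.08, dnaJ by 3.07 ± 0.09 and the protease gene hslV (label menA, 55.9% of the row, with 43.1% in hslU) by 2.22 ± 0.06. The SoxRS superoxide list had 9 of 10 members higher and none lower (median 2.53, adjusted p = 1.6e-15; adjusted p = 0.020 with an estimated correlation). Its members included nfsA (label grxA), a nitroreductase gene, at 4.14 ± 0.07, rimK (label nfsA) at 3.89 ± 0.11, fumC (label rstB, 71% of the row, with 29.3% in tus) at 4.14 ± 0.17 and zwf (label edd), coding for glucose-6-phosphate dehydrogenase, at 2.16 ± 0.08.

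The OxyR peroxide list had 8 of 13 members higher and 2 lower (median 0.84, camera adjusted p = 0.0015; adjusted p = 0.34 with an estimated correlation). The 4 with the smallest p included 3 rows of the suf operon for iron-sulfur cluster assembly. Values were sufD (label sufE) at 2.28 ± 0.12 and sufB (label sufD) at 2.05 ± 0.11. The row shared by sufC and sufD (label sufS) stood at 2.41 ± 0.08 and dps (label glnH, 53.1% of the row) at 2.04 ± 0.12. RpoS general stress genes had 8 of 9 members higher and 1 lower (median 2.92, adjusted p = 0.00042; adjusted p = 0.34 with an estimated correlation). Among them were poxB (label ltaE, 76.2% of the row, with 20.2% in ltaE) at 4.64 ± 0.24 and the catalase gene katE (label cedA) at 4.10 ± 0.26. TCA cycle genes had 12 of 15 members higher and 1 lower (median 1.45, adjusted p = 2.9e-08; adjusted p = 0.30 with an estimated correlation). There, gltA (label ybgD, 72.5% of the row), coding for citrate synthase, stood at 2.85 ± 0.14 and sucA (label sucA, 71.4% of the row, with 28.1% in sucB) at 2.78 ± 0.12. Arginine synthesis and transport had 13 of 14 members higher and 1 lower (median 1.65, adjusted p = 7.7e-07; adjusted p = 0.30 with an estimated correlation). Examples were argF (label xynR) at 3.70 ± 0.19 and argH (label argC) at 2.71 ± 0.16.

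Ribosomal protein genes had 20 of 21 members lower and none higher (median -0.90, and -0.55 by library totals alone, camera adjusted p = 2.9e-10; adjusted p = 0.30 with an estimated correlation). Examples were rpsD (label yhdN) at -1.03 ± 0.07 and rpsB at -0.90 ± 0.06. Cell division and peptidoglycan synthesis genes had 16 of 28 members lower and 2 higher (median -0.25, adjusted p = 0.0026; adjusted p = 0.34 with an estimated correlation). There, ftsW stood at -1.07 ± 0.06 and mraZ at -0.88 ± 0.06. By library totals alone the median of this list was 0.10 and the call was lost (adjusted p = 0.069). For all 9 lists described for 30 min, counts adjusted over the list alone were the same as those adjusted over all rows. By deposited label, as planned, 10 of 30 lists were called, against 9 of 29 at the displaced positions. With an estimated correlation camera called 0 and 3, where 7 and 4 had an unadjusted p under 0.05.

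**Figure D2:**
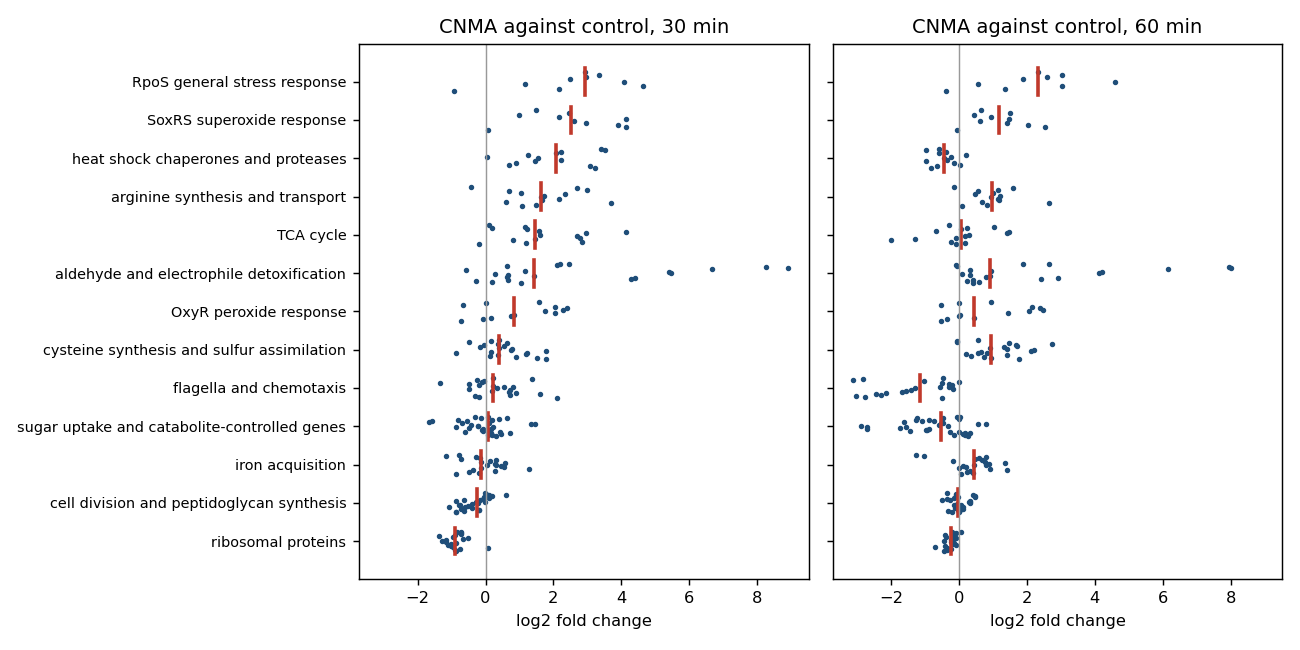
Log2 fold change of CNMA against control (horizontal axis) for members of gene lists placed at the displaced positions, at 30 and 60 min; each point is a member and each bar the list median. The heat shock median is 2.08 at 30 min and -0.44 at 60 min, and that of aldehyde and electrophile detoxification 1.44 and 0.92.

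Other large increases at 30 min were those of torA (label torC, 68.3% of the row, with 31.8% in torC), for trimethylamine N-oxide reductase, at 6.28 ± 0.16, yhbW (label yhbU) at 5.84 ± 0.16 and nemA (label ydhL, 62.9% of the row), for N-ethylmaleimide reductase, at 5.47 ± 0.16. The row labelled comR, of which 40.8% lay in bhsA and 34.9% in ldtC, rose by 5.72 ± 0.19, and the row labelled poxB, shared by poxB and hcr, by 5.48 ± 0.24. The largest decrease was that of nmpC (label insH-2), a porin gene next to an insertion sequence, at -4.85 ± 0.25. That value is uncertain because insertion sequence copies share reads. Further decreases were those of ymcE (label cspH, 60.6% of the row, with 51.6% in ymcF) at -3.17 ± 0.19, borD (label rrrD, 59% of the row, with 31.3% in rzpD) at -2.84 ± 0.10, yafT at -2.53 ± 0.15, the copper efflux gene cusA (label cusA, 74.6% of the row, with 22.2% in pheP) at -2.50 ± 0.09, insK (label yiaG), also an insertion sequence gene, at -2.45 ± 0.11 and yagU (label paoA, 55.5% of the row) at -2.36 ± 0.14.

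In total, 2793 of 4300 rows were called at 30 min by edgeR's quasi-likelihood test, 1428 higher and 1365 lower with CNMA. Of these, 926 had an absolute log2 fold change of at least 1. Scaling to library totals alone moved the median of all rows from 0.0061 to 0.36 and the split to 2277 higher and 733 lower, so directions are relative to the TMM scale. In stretch 1, where labels were taken as in place, 167 of 235 rows were called, 50 higher and 117 lower. The authors' deposited table has 2846 rows with adjusted p under 0.05 at 30 min, 1433 higher and 1413 lower.

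**Figure D3:**
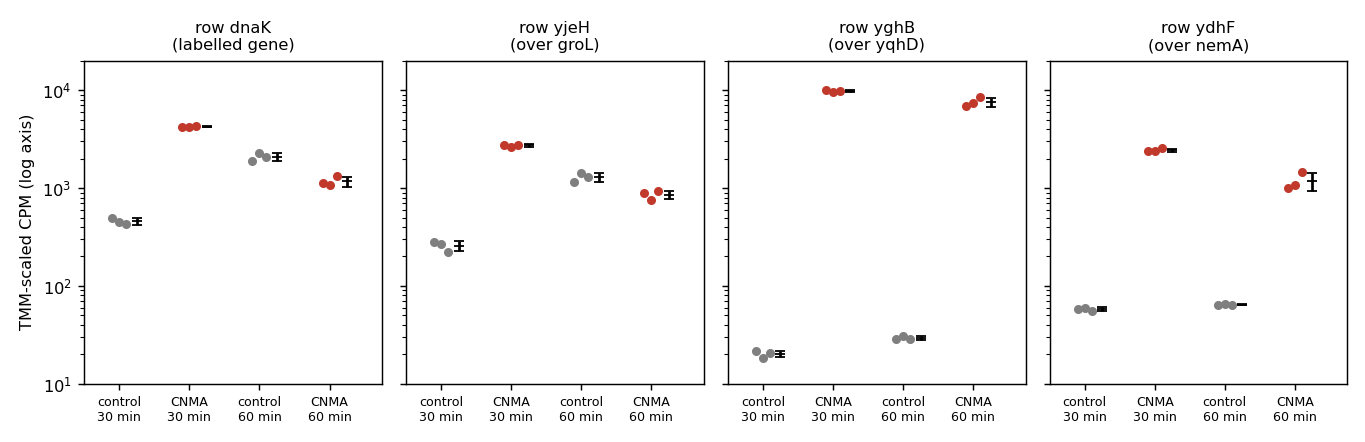
TMM-scaled CPM on a log axis (vertical) in each of the 12 libraries for the rows labelled dnaK, yjeH (over groL), yghB (over yqhD) and ydhF (over nemA), by group (horizontal axis); points are libraries, and the marks beside them are group means with SD (n = 3). For yqhD (label yghB), means are 20.2 and 9844 CPM without and with CNMA at 30 min, and 29.3 and 7594 CPM at 60 min.

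The second comparison asked the same after 60 min. The largest increase was again that of yqhD (label yghB), from 29.3 ± 1.20 to 7594 ± 816 CPM (SD, n = 3), a log2 fold change of 8.02 ± 0.10 (SE). The row labelled yqhC, shared by dkgA and yqhD, rose by 7.96 ± 0.14. The chaperone gene dnaK was now lower with CNMA than without. It stood at 2072 ± 199 CPM in control and 1170 ± 133 CPM with CNMA, a log2 fold change of -0.82 ± 0.08. By camera with the preset correlation, flagellar genes and genes for sugar uptake were lower with CNMA than in control at 60 min. Genes for cysteine synthesis and iron acquisition were higher. With an estimated correlation none of these 4 calls held (adjusted p = 0.15, 0.080, 0.24 and 0.60), and the iron call was also lost where 80% of the row was required (adjusted p = 0.094). The flagellar switch gene fliM (label fliK, 69.2% of the row, with 31.1% in fliN) stood at 22.9 ± 3.32 CPM in control and 3.24 ± 0.551 CPM with CNMA, a log2 fold change of -2.83 ± 0.16. At 30 min its means were 1.67 CPM in control and 4.34 CPM with CNMA. From 30 to 60 min the list medians were 1.67 for flagella and 1.17 for sugar uptake in control cultures, and -0.15 and 0.40 in CNMA cultures. The lower values at 60 min thus went with a rise in control more than with a fall in CNMA cultures.

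Of the aldehyde and electrophile list, 16 of 21 members were higher at 60 min and none lower (median 0.92, camera adjusted p = 1.1e-28; adjusted p = 0.030 with an estimated correlation). There, yqhC (label metC) stood at 6.16 ± 0.13 and nemR (label sodC) at 4.13 ± 0.09. SoxRS genes had 9 of 10 members higher and none lower (median 1.18, adjusted p = 1.2e-07; adjusted p = 0.080 with an estimated correlation). Members included nfsA (label grxA) at 2.53 ± 0.06 and zwf (label edd) at 0.93 ± 0.07. OxyR genes had 7 of 13 higher and 3 lower (median 0.44, adjusted p = 9.6e-05; adjusted p = 0.28 with an estimated correlation). The 4 with the smallest p were suf rows, such as sufD (label sufE) at 2.46 ± 0.11 and sufS (label lpp) at 2.06 ± 0.10. RpoS genes had 8 of 9 higher and 1 lower (median 2.32, adjusted p = 3.9e-05; adjusted p = 0.28 with an estimated correlation). Members included katE (label cedA) at 4.59 ± 0.28 and the transketolase gene tktB (label talA) at 3.04 ± 0.22. Arginine genes had 11 of 14 higher and none lower (median 0.97, adjusted p = 3.1e-05; adjusted p = 0.28 with an estimated correlation). Here argF (label xynR) stood at 2.66 ± 0.18.

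Cysteine synthesis and sulfur assimilation had 17 of 21 members higher at 60 min and none lower (median 0.94, camera adjusted p = 9.6e-05; adjusted p = 0.24 with an estimated correlation). Sulfite reductase gene cysI (label sokX) stood at 2.73 ± 0.29, the sulfate transport gene cysW (label cysM, 77.3% of the row, with 23.9% in cysA) at 2.21 ± 0.20 and the taurine dioxygenase gene tauD (label tauC) at 1.76 ± 0.14. Iron acquisition had 13 of 21 members higher and 2 lower (median 0.44, adjusted p = 0.016; adjusted p = 0.60 with an estimated correlation), and 3 lower when adjusted over the list alone. Its members with the smallest p were genes for the siderophore enterobactin and ferric siderophore receptors. Of these, fepA (label entD) stood at 1.41 ± 0.10, entA (label entB) at 1.35 ± 0.13 and fiu (label ybiX) at 0.77 ± 0.08. With members required to fill 80% of their row, the iron list was no longer called (adjusted p = 0.094).

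Heat shock genes had 11 of 13 members lower at 60 min and 1 higher (median -0.44, camera adjusted p = 0.0021; adjusted p = 0.34 with an estimated correlation). Members included htpG (label recR) at -0.98 ± 0.08, groS (label fxsA) at -0.97 ± 0.08 and hslU (label rraA) at -0.60 ± 0.07. Flagella and chemotaxis had 16 of 22 members lower and none higher (median -1.17, adjusted p = 1.3e-05; adjusted p = 0.15 with an estimated correlation). Members included flgD (label flgB) at -3.05 ± 0.20, flgF (label flgE, 62.5% of the row, with 33.8% in flgE) at -2.45 ± 0.21 and flgG (label flgF) at -2.16 ± 0.15. Sugar uptake and catabolite-controlled genes had 20 of 33 lower and 3 higher (median -0.53, adjusted p = 2.2e-05; adjusted p = 0.080 with an estimated correlation). Examples were the galactose transport gene mglA (label mglC, 61.5% of the row, with 32.5% in mglB) at -2.71 ± 0.18, the ribose transport gene rbsA (label kup, 71.3% of the row, with 22.5% in rbsD) at -1.62 ± 0.08 and the mannose transport gene manX (label yoaE, 62.4% of the row, with 27.6% in manY) at -1.44 ± 0.07. Ribosomal protein genes had 16 of 21 lower and none higher (median -0.23, and -0.15 by library totals alone, adjusted p = 0.036; adjusted p = 0.69 with an estimated correlation). There, rplM (label sspB) stood at -0.71 ± 0.10. The call was lost without CNMA at 60 min replicate 3 (adjusted p = 0.086), without control at 60 min replicate 2 (0.054) or 3 (0.064), and without control at 30 min replicate 1 (0.053), 2 (0.051) or 3 (0.053).

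The TCA cycle list, called at 30 min, had 3 of 15 members higher and 4 lower at 60 min (median 0.049, and 0.13 by library totals alone, camera adjusted p = 0.80, with the test pointing down). There the succinate dehydrogenase gene sdhC (label ybgU) stood at -2.01 ± 0.09, while fumC (label rstB) stood at 1.47 ± 0.16. Further increases at 60 min were those of torA (label torC) at 6.01 ± 0.16, the row labelled yqhD at 5.42 ± 0.15, the row labelled comR at 5.03 ± 0.19, katE (label ydjO) at 4.32 ± 0.24 and nemA (label ydhF) at 4.20 ± 0.12. The row labelled yqhD lay 68.2% in yqhG and 14.7% in dkgA. With CNMA at 60 min it held 321 CPM, against 5432 CPM in the row labelled yqhC, shared by dkgA and yqhD. Its rise can therefore not be assigned to yqhG. Further decreases were those of nmpC at -4.80 ± 0.20 (label insH-2) and -4.63 ± 0.18 (label nmpC, 65.2% of the row), ompF (label aspC) at -2.85 ± 0.06, flgB (label flgA, 63.2% of the row, with 34.2% in flgC) at -2.77 ± 0.27 and the aspartase gene aspA (label dcuA, 71.5% of the row) at -2.57 ± 0.12. Rows labelled mglA, 43.1% in mglB, and ebgA, 45.8% in ygjI, both stood at -2.61, with SEs of 0.12 and 0.14.

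At 60 min, 2271 of 4300 rows were called by edgeR's quasi-likelihood test, 1074 higher and 1197 lower. Of these, 605 had an absolute log2 fold change of at least 1. The larger side turned to 1269 higher and 992 lower by library totals alone, and to 844 higher and 770 lower among rows with a mean of at least 10 CPM, so which side is larger depends on the setting. In stretch 1, 120 of 235 rows were called, 58 higher and 62 lower. Except for the iron list, counts adjusted over the list alone did not differ for the 11 lists called. By deposited label 9 of 30 lists were called, and with an estimated correlation each placement called 1 list. These were different lists in opposite directions: sugar uptake, lower, by label (adjusted p = 0.038) and the aldehyde list, higher, at the displaced positions. The authors' deposited table has 1854 rows with adjusted p under 0.05 at 60 min, 888 higher and 966 lower. With only the compared libraries in the edgeR fit, 1909 rows were called at 60 min, 960 higher and 949 lower. The same change of fit gave 3015 rows at 30 min. The counts thus depend on whether libraries of the other time share the fit.

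Across rows, which are not independent replicates, the log2 fold changes at 30 and 60 min, which share no library, had a Pearson correlation of 0.63 and a Spearman correlation of 0.53. Both times called 1664 rows, of which 699 were higher at both and 675 lower at both, where independent lists would give 357 and 380. Another 170 rows were higher at 30 and lower at 60 min, and 120 the reverse.

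**Figure D4:**
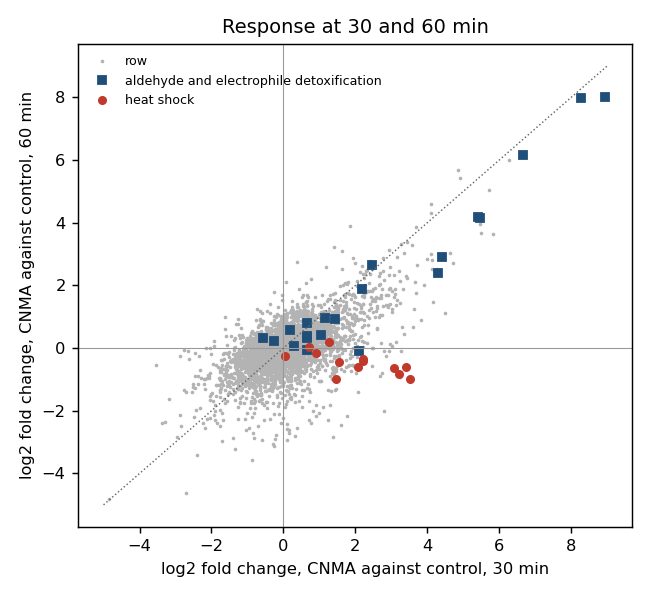
Log2 fold change of CNMA against control at 60 min (vertical axis) against that at 30 min (horizontal axis) for the 4300 rows tested; each point is a row, and members of the named lists are coloured. The correlation across rows is 0.63, and 290 rows called at both times have opposite directions.

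The third comparison tested whether the CNMA effect differed between the times. The 5 largest downward differences among rows named by the rule were in heat shock and flagellar genes. The effect at 60 min minus that at 30 min was -4.48 ± 0.11 for groS (label fxsA), -4.04 ± 0.12 for dnaK, -4.00 ± 0.14 for groL (label yjeH), -4.20 ± 0.25 for fliM (label fliK) and -4.05 ± 0.32 for flgF (label flgE). Both flagellar rows were higher with CNMA at 30 min, at 1.37 ± 0.19 and 1.60 ± 0.25, and lower at 60 min. In the other direction, the row labelled cydA was shared by cydB and cydA of the cytochrome bd oxidase. It went from -1.63 ± 0.11 to 1.00 ± 0.11, a difference of 2.64 ± 0.16. The row labelled cydB, 29.8% in cydB and 25.8% in ybgE, differed by 2.22 ± 0.15. Rows mostly outside a single gene completed the set, labelled yccA at 2.17 ± 0.18, yfcZ (25.3% in fadL) at 2.15 ± 0.16 and cas3 (28.4% in cysI) at 2.05 ± 0.29.

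All 13 heat shock members had a lower effect at 60 min (median -2.58, camera adjusted p = 7.1e-54; adjusted p = 0.0016 with an estimated correlation). TCA cycle genes had 11 of 15 lower and none higher (median -1.55, adjusted p = 2.8e-14; adjusted p = 0.084 with an estimated correlation), and 12 adjusted over the list alone. SoxRS genes had 9 of 10 lower (median -1.39, adjusted p = 6.4e-08; adjusted p = 0.077 with an estimated correlation). Flagellar genes had 16 of 22 lower and 1 higher (median -1.70, adjusted p = 3.3e-05; adjusted p = 0.17 with an estimated correlation). Sugar uptake had 18 of 33 lower and 2 higher (median -0.45, adjusted p = 0.0095; adjusted p = 0.24 with an estimated correlation). Arginine genes had 10 of 14 lower (median -0.68, adjusted p = 0.031; adjusted p = 0.61 with an estimated correlation), with 1 higher when adjusted over the list alone. Cpx envelope stress had 4 of 7 lower (median -0.24, adjusted p = 0.031; adjusted p = 0.29 with an estimated correlation), and 5 adjusted over the list alone. Effects were higher at 60 min for 19 of 21 ribosomal protein genes and lower for 1 (median 0.61, adjusted p = 3.6e-08; adjusted p = 0.29 with an estimated correlation). Cell division had 17 of 28 higher and 4 lower (median 0.32, adjusted p = 0.00022; adjusted p = 0.24 with an estimated correlation), and 19 and 5 adjusted over the list alone. By library totals alone its median was near 0, at 0.044. Iron acquisition had 12 of 21 higher and 1 lower (median 0.59, adjusted p = 0.00099; adjusted p = 0.52 with an estimated correlation). Methionine synthesis had 8 of 11 higher and 1 lower (median 0.98, adjusted p = 0.0033; adjusted p = 0.080 with an estimated correlation), and 2 lower adjusted over the list alone. Type 1 fimbriae and curli had 3 of 7 higher (median 0.73, adjusted p = 0.0098; adjusted p = 0.29 with an estimated correlation). Other medians that moved by library totals alone were 0.34 for ribosomal protein, 0.31 for iron, 0.46 for fimbriae and curli, -0.72 for sugar uptake and -0.51 for Cpx genes. The aldehyde list was not called (median -0.34, and -0.61 by library totals alone, adjusted p = 0.068), though 10 of its 21 members were lower and 3 higher.

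The interaction called 1989 rows by edgeR's quasi-likelihood test, 887 with a higher and 1102 with a lower effect at 60 min. Of these, 627 differed by a log2 of at least 1. In stretch 1 the split was 86 higher and 31 lower. By library totals alone the split was 445 higher and 1688 lower, and the median of all rows was -0.31.

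The fourth comparison measured what time in culture changed without CNMA. Between 30 and 60 min, genes for sugar uptake and heat shock rose in the control cultures. Flagellar and iron acquisition genes were also called higher with the preset correlation, but not with an estimated one (adjusted p = 0.11 and 0.44). The galactitol uptake gene gatC (label gatD, 50% of the row, with 27.4% in gatB) rose from 8.63 ± 0.709 to 148 ± 17.5 CPM (SD, n = 3), a log2 fold change of 4.10 ± 0.12, and the row shared by gatD and gatC (label insF-5) by 4.07 ± 0.12. Flagellar rows rose by 4.42 ± 0.33 for flgB (label flgA), 3.77 ± 0.18 for fliM (label fliK) and 3.60 ± 0.24 for flgF (label flgE). The phosphate-binding protein gene pstS (label pstA) fell by 2.10 ± 0.19 on the log2 scale, ydeA (label yneJ, 66.1% of the row) by 2.10 ± 0.10, msrP (label hprR, 60.4% of the row, with 39.6% in msrQ) by 2.02 ± 0.11 and proP (label yjcZ), for an osmolyte transporter, by 1.91 ± 0.08. The row labelled crfC, shared by rdcB and proP, fell by 2.07 ± 0.08.

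Sugar uptake had 27 of 33 members higher and 2 lower in control at 60 min (median 1.17, camera adjusted p = 1.8e-20; adjusted p = 0.0039 with an estimated correlation), and 3 lower adjusted over the list alone. Heat shock had 12 of 13 higher (median 1.17, adjusted p = 4.2e-17; adjusted p = 0.042 with an estimated correlation), and 13 adjusted over the list alone. Iron acquisition had 20 of 21 higher (median 1.15, adjusted p = 1.2e-08; adjusted p = 0.44 with an estimated correlation). Flagella had 17 of 22 higher and 2 lower (median 1.67, adjusted p = 4.0e-08; adjusted p = 0.11 with an estimated correlation). TCA cycle genes had 10 of 15 higher and 1 lower (median 0.35, adjusted p = 8.0e-05; adjusted p = 0.49 with an estimated correlation). Purine and pyrimidine synthesis had 11 of 17 higher and 3 lower (median 0.70, adjusted p = 0.0010; adjusted p = 0.44 with an estimated correlation). Arginine genes had 10 of 14 higher (median 0.63, adjusted p = 0.020; adjusted p = 0.69 with an estimated correlation). OxyR genes had 9 of 13 higher and 1 lower (median 0.54, adjusted p = 0.022; adjusted p = 0.69 with an estimated correlation), and 2 lower adjusted over the list alone. Ribosomal protein genes had 17 of 21 lower (median -0.33, and -0.16 by library totals alone, adjusted p = 0.00079; adjusted p = 0.69 with an estimated correlation). Fimbriae and curli had 3 of 7 lower (median -0.73, adjusted p = 0.011; adjusted p = 0.46 with an estimated correlation), and 4 adjusted over the list alone. In all, 2287 rows were called, 1216 higher and 1071 lower at 60 min, and 1683 and 659 by library totals alone, where the median was 0.16.

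The fifth comparison, 60 against 30 min in CNMA cultures, combines culture age with length of exposure. Iron acquisition genes rose and heat shock genes fell. The enterobactin receptor gene fepA (label entD) rose from 15.1 ± 0.510 to 116 ± 10.8 CPM (SD, n = 3), a log2 fold change of 2.94 ± 0.11. The row labelled cydA, shared by cydB and cydA, rose by 2.94 ± 0.12, gatC (label gatD) by 2.92 ± 0.11, the row labelled insF-5 by 2.88 ± 0.12 and the row labelled cas3 by 2.79 ± 0.20. Decreases on the log2 scale were -3.13 ± 0.13 for ycjY (label ycjG) and -3.03 ± 0.29 for astC (label astD, 60.7% of the row, with 39.6% in astA), a gene of arginine breakdown. The row labelled yidE, which held parts of the small chaperone genes ibpA and ibpB, stood at -3.01 ± 0.09. The row labelled mhpT, 44.6% in yaiL and 34% in mhpT, stood at -2.82 ± 0.12. For frmB (label yaiL), a gene of formaldehyde breakdown, the value was -2.62 ± 0.13.

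All 21 iron acquisition members were higher at 60 than at 30 min with CNMA (median 1.37, camera adjusted p = 2.9e-26; adjusted p = 0.036 with an estimated correlation). All 13 heat shock members were lower (median -1.41, adjusted p = 2.2e-21; adjusted p = 0.026 with an estimated correlation). Sugar uptake had 17 of 33 higher and 3 lower (median 0.40, adjusted p = 2.2e-10; adjusted p = 0.025 with an estimated correlation). Methionine synthesis had 10 of 11 higher (median 0.65, adjusted p = 0.00063; adjusted p = 0.036 with an estimated correlation). TCA cycle genes had 11 of 15 lower and 1 higher (median -0.86, adjusted p = 4.0e-06; adjusted p = 0.28 with an estimated correlation). SoxRS genes had 8 of 10 lower (median -0.71, adjusted p = 1.3e-05; adjusted p = 0.087 with an estimated correlation). Aldehyde genes had 12 of 21 lower and 3 higher (median -0.33, adjusted p = 0.0028; adjusted p = 0.40 with an estimated correlation). Cell division had 18 of 28 higher and 1 lower (median 0.28, adjusted p = 0.0011; adjusted p = 0.28 with an estimated correlation). Purine and pyrimidine synthesis had 12 of 17 higher and 2 lower (median 0.47, adjusted p = 0.0023; adjusted p = 0.28 with an estimated correlation). Cysteine synthesis had 12 of 21 higher and 2 lower (median 0.56, adjusted p = 0.0027; adjusted p = 0.28 with an estimated correlation). Ribosomal protein genes had 15 of 21 higher and none lower (median 0.31, adjusted p = 0.0028; adjusted p = 0.59 with an estimated correlation), where 19 were higher and 1 lower adjusted over the list alone. OxyR genes had 7 of 13 higher and 3 lower (median 0.24, adjusted p = 0.045; adjusted p = 0.59 with an estimated correlation). Adjusted over the list alone, the remaining differences were 4 higher and 13 lower aldehyde genes, 21 higher cell division genes, 13 higher purine and pyrimidine genes, 13 higher and 3 lower cysteine genes, 8 higher OxyR genes and 4 lower sugar uptake genes. By library totals alone medians were 0.17 for cell division, 0.20 for ribosomal protein and 0.14 for OxyR genes. In all, 2044 rows were called, 1013 higher and 1031 lower at 60 min, and 722 and 1298 by library totals alone, where the median was -0.14.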

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

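Of the tests below, the splits of the interaction were planned before their result was seen, as was leaving out single libraries for the heat shock list. The tests on scaling and on culture age were chosen after the result was seen.

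The interaction between CNMA and time drew attention because 1989 rows differed between the effects at 30 and 60 min. Among 100 drawn splits of the libraries within each time, 1, the real one, called as many, and the highest other split called 1774 rows. This does not exclude chance for the interaction: a split that mixes a time also breaks the CNMA effect there and moves it into the residual, so it does not represent an absent interaction. The highest other split kept all 6 libraries of 30 min in their true groups and 2 of those of 60 min, so it holds the 30 min effect. The 15 other drawn splits that left 1 time whole called at least 165 rows, and the 84 that mixed both times called 0 at most.

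Single rows that stood out by the same interaction test were cydA at 2.64, cydB at 2.22, yccA at 2.17, yfcZ at 2.15 and cas3 at 2.05 as log2 differences upward. Downward, they were fxsA (over groS) at -4.48, fliK (over fliM) at -4.20, flgE (over flgF) at -4.05, dnaK at -4.04 and yjeH (over groL) at -4.00. These names are deposited labels.

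The turn of the heat shock list, higher with CNMA at 30 min (median 2.08) and lower at 60 min (median -0.44, a call lost with an estimated correlation, adjusted p = 0.34), was weighed further. Scaling of the libraries is argued against, since the median at 60 min was at most -0.36 under the other scalings and that at 30 min at least 2.05. A single library is argued against too, since the median at 60 min was at most -0.38 without each library in turn. A rise with culture age in the controls fits as part of the turn: the list median rose by 1.17 (SE over the 13 members 0.28) between control at 30 and 60 min, but both values use the same control libraries at 60 min. It is argued against as the whole cause, since the effect at 30 min minus the control change had a median of 0.95 (SE over members 0.16), above 0 for 12 of 13 members. That difference amounts to CNMA at 30 min against control at 60 min. Members share regulation and libraries, so an SE over them leaves out the spread between cultures. The rest of the turn is the fall in CNMA cultures over the same interval (median -1.41, all 13 members lower, adjusted p = 0.026 with an estimated correlation). Why it fell there, by the end of an early response to CNMA or otherwise, stays open.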

How the results depend on the processing

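Tests on lists at displaced positions and fits without the 10 largest rows were chosen after seeing the data. Of 4133 alternative values for the 174 named values, 4089 kept direction and call, 44 lost the call and 0 reversed. Of those lost, 35 fell under the fold minimum, 4 were lost by library totals, 2 by library totals without the 10 largest rows, and 1 each without CNMA at 30 min replicate 3, control at 30 min replicate 1 and control at 30 min replicate 3. The filter at a mean of 10 CPM gave only 143 of the 174 values, and the fit of only the compared libraries 162. Named values missing there were not tested under that setting. Requiring an absolute log2 fold change of at least 1 left 926 rows at 30 min, 605 at 60 min, 627 in the interaction, 486 for control and 400 for CNMA over time, as its construction implies. All other settings kept each count of rows within 1.5 times. The larger side of the split was less stable, and only in the interaction did every setting keep it. With DESeq2 size factors it turned to 1370 higher and 1434 lower at 30 min, and to 1075 higher and 989 lower for CNMA over time. With a mean of at least 10 CPM it turned to 823 higher and 860 lower for control over time. At 60 min it turned under several settings, including leaving out any control library at 30 min (1120 higher and 1082 lower without replicate 1). Leaving out 1 library at a time gave 2534 to 2900 rows at 30 min, 1996 to 2316 at 60 min, 1776 to 2030 in the interaction, 2014 to 2387 for control and 1741 to 2185 for CNMA over time.

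By deposited label, 10 lists were called at 30 min and 9 at 60 min, with ranges of 9 to 11 and 9 to 10 when 1 library was left out. With the correlation estimated, camera called 0 lists at 30 min (7 at an unadjusted p under 0.05) and 1 at 60 min (sugar uptake, lower), while fry, which compares a list with no other genes, called 22 and 21. At the displaced positions the calls were 9 and 11, with an estimated correlation 3 and 1 (at 60 min aldehyde detoxification, higher), and with 80% of the row required 12 and 10. Calls therefore depend on how correlated members are taken to be. The median estimated correlation of lists was 0.14 at the displaced positions and 0.050 by label at 30 min.

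Median log2 fold changes of all rows moved with scaling, and the cause was not tested beyond the weighing under the other observations. By library totals they were 0.36 at 30 min, 0.067 at 60 min, -0.31 in the interaction, 0.16 for control and -0.14 for CNMA over time, and without the 10 largest rows 0.26, 0.055, -0.22, 0.10 and -0.11. With DESeq2 size factors they were -0.025 at 30 min, 0.00029 in the interaction, -0.029 for control and -0.016 for CNMA over time. The correlation of effects across rows was 0.70 among rows with a mean of at least 10 CPM, and the cause was not tested. It was 0.60 without CNMA at 60 min replicate 3 and 0.66 without control at 60 min replicate 1, the lowest and highest with 1 library left out.

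Replicate numbers did not pair the samples: of 18 same-number pairs, 4 had deviations correlated over 0.1 (range -0.43 to 0.34), and 3 of 12 libraries correlated best with their own number. Pairs with different numbers ranged from -0.50 to 0.49, the highest being control at 60 min replicate 1 with CNMA at 60 min replicate 2. Whether groups share some other structure, which a replicate block would not take up, was not tested. With the replicate block, calls were 2748, 2214, 1937, 2204 and 1995 rows in the 5 comparisons and 10 and 9 lists. Library totals were 17297933 to 25458608 counts, and no other depth was simulated, so what depth limits was not measured.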

Other observations

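Lists that were not called against control at either time, placed at the displaced positions, are given as higher and lower members at 30 min and then at 60 min. Multidrug efflux and the Mar-Rob regulon had 8 and 5 of 17, then 7 and 2. In it, the efflux channel gene tolC (label yqiB) stood at 1.84 and 1.10, and the efflux gene emrA (label ygaZ) at 1.94 and 0.74, both chosen after their values were seen. Copper and zinc efflux had 5 and 1 of 8, then 3 and 2. SOS genes of DNA damage had 2 and 3 of 13, then 2 and 4. Cpx genes had 5 and 1 of 7, then 3 and 2, and sigmaE genes 2 and 5 of 12 at both times. Colanic acid synthesis and the Rcs regulon had 4 and 1 of 13, then 0 and 1. Fimbriae and curli had 0 and 5 of 7, then 3 and 0. Glutamate-dependent acid resistance had 0 and 3 of 4, then 0 and 2, with hdeB (label slp, 57.7% of the row) at -2.36 ± 0.13 and -0.89 ± 0.12. By deposited label this list was called at 30 min (adjusted p = 0.013; adjusted p = 0.16 with an estimated correlation).

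Aerobic respiration had 9 and 5 of 14 members higher and lower, then 9 and 3, and anaerobic respiration 7 and 5 of 19, then 7 and 6. Methionine synthesis had 2 and 7 of 11, then 8 and 0, and was called by deposited label at 60 min (adjusted p = 0.0069; adjusted p = 0.18 with an estimated correlation). Branched-chain amino acid synthesis had 2 and 5 of 15, then 5 and 9. Histidine and tryptophan synthesis had 4 and 5 of 12, then 0 and 8. Purine and pyrimidine synthesis had 4 and 7 of 17, then 3 and 11. Fatty acid degradation had 5 and 2 of 8, then 0 and 4, and fatty acid synthesis 3 and 4 of 9, then 1 and 5. The phage shock list, by label, had 1 and 1 of 3 at both times. Lists called against control at 1 time had these members at the other: at 30 min flagella had 9 and 1 of 22, iron acquisition 5 and 8 of 21, sugar uptake 6 and 8 of 33 and cysteine synthesis 13 and 2 of 21, and at 60 min cell division had 7 and 8 of 28. The camera test pointed down where the median was positive for SOS, histidine and tryptophan, fatty acid degradation and sugar uptake genes at 30 min and for anaerobic respiration at 60 min, and up where it was negative for Cpx genes at 60 min. None of these was called. Adjusted over each list alone, Rcs genes had 2 and 0 at 30 min, SOS genes 1 and 3, iron acquisition 5 and 7 and sugar uptake 6 and 7. At 60 min fatty acid degradation had 0 and 5, fatty acid synthesis 1 and 6, anaerobic respiration 7 and 7 and methionine synthesis 8 and 1.

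For the comparisons of 3 libraries with 3, the 6 libraries allow 10 splits, too few for a share under 0.05. In each, 1 split, the real one, gave the most rows: 2793 at 30 min, 2271 at 60 min, 2287 for control over time and 2044 for CNMA over time. By edgeR, the highest other split gave 0 in each, with 66, 485, 283 and 256 rows at an unadjusted p under 0.05. The tests for control and CNMA over time were set before their result was seen, and those at 30 and 60 min after.

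Labels of abundant genes stood on rows with few counts. Both tests of this pattern were chosen after it was seen. Reads counted on the other strand with labels in place are argued against in stretches 2 and 3. There 25 of 28 windows had their best displacement within 300 bases of that estimated from other windows of their stretch (800 in stretch 2, 1850 and 2000 in stretch 3), where labels in place would favour no displacement far from 0. A candidate explanation is that intervals and aligned genome came from versions that differ by inserted bases, which fits 26 of 28 windows near 1 value per stretch. The other 2 were the window across the second boundary, at 1700 bases, and another at -3750. All 8 gene group scans of the displaced stretches were also higher at the displacement than at 0. Those of the heat shock list used the 30 min log2 ratio and scored 0.050 against 0.042 in stretch 2 and 0.124 against 0.0 in stretch 3. They are not independent of the heat shock result at 30 min. No biological explanation was tested, and the exact boundaries stay open.

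Most rows were higher with CNMA at 30 min when scaled to library totals, with a median of 0.36. The 10 largest rows held 21.7% ± 0.350 of counts in control at 30 min and 16.1% ± 0.345 in CNMA at 30 min (SD, n = 3). These 10 rows are argued against as the whole cause, since without them the median was still 0.26. That test was set before its result was seen, though after the data had been examined. Other abundant rows stayed in, so it cannot decide on abundant rows as a group. The 10 rows may account for part of the shift. By library totals the ribosomal protein list had a median of -0.55 at 30 min, so the make-up of the counted RNA did differ between the groups. Whether this reflects a change in the total RNA of the cells with CNMA stays open and was not tested.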
